A study of Mus musculus with 12 samples.

How the data were processed

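The series profiled dorsal root ganglia of mice in which Advillin-Cre, active in peripheral sensory neurons, switches on an HA-tagged form of a large-subunit ribosomal protein (RiboTag). Anti-HA immunoprecipitation (IP) recovers RNA bound to tagged ribosomes, and the input was taken here as RNA of the ganglion lysate before it. The labels call the input total RNA, but the extraction text given for the input samples describes the immunoprecipitation, so how the input RNA was prepared stays uncertain. Ganglia came from mice with or without sciatic nerve injury. The labels name 12 samples in 4 groups of 3, which are IP injured, IP uninjured, input injured and input uninjured. The time after injury, the number of animals and any pooling are not given in the sources used here.

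Libraries were made with a nanopore PCR-cDNA barcoding kit, per the labels. The deposited table holds estimated counts per transcript, which need not be whole. Between 3.00% and 11.4% of all 101744 values in a sample, zeros included, were not whole. The submitters' processing notes name minimap2 and Salmon and the genome build names GRCm39 and mm39. The roles, versions and settings of these tools are not given in the sources used here. The table lists 101744 Ensembl mouse transcript IDs, of which 35917 had a count in at least 1 sample. The files do not pair these IDs with gene names, and 0 IDs matched the gene tables used here. Sums per gene, the 35 gene lists fixed before the data were examined, the genes that were always to be reported and isoform usage were therefore not analysed here.

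The planned test was edgeR's quasi-likelihood test with 3 replicates per group. It was replaced after the data were seen, because the 3 samples of each group had nearly equal totals and a median spread close to counting noise. They were therefore treated as 3 portions of 1 sample, their estimated counts were summed and rounded to whole numbers, and each group counted as 1 sample. No difference between conditions has a replicate check, and no p-value across transcripts is given as evidence on the conditions. Spread between the 3 was measured per transcript as the chi-square statistic of their estimated counts, and its median was divided by the median that counting noise alone gives. Portions were taken to agree within counting noise where the chi-square p was above 0.01 in all 4 groups. The labels list the 3 as separate samples, so fits that take them as replicates were run as alternatives. Whether the replicate numbers pair the samples was checked by correlating deviations from the group means across 498 transcripts. Between injured and uninjured input, the same-numbered samples had r of 0.191, 0.258 and 0.169, and differently numbered ones -0.253 to 0.0372. Differently numbered samples of the IP groups reached 0.458. Over all groups the mean r was 0.00805 for same-numbered and -0.00479 for differently numbered samples. These values cannot settle whether the numbers are pairs for injury in input, and the reported counts do not use pairs. The labels do not say what the numbers share. In the other comparisons at least 1 same-numbered pair had a negative r, and the numbers were not taken as pairs.

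Library sizes were the totals over all transcripts, scaled with TMM factors from the summed counts of transcripts that passed edgeR's filterByExpr. A first computation took the factors over all transcripts and gave unstable splits when a portion was left out, so the filter, which the plan named, was put back after those values were seen. A transcript was compared where the higher group reached 10 CPM after scaling. It was counted as higher or lower where it differed at least 2-fold, the 95% counting interval of the ratio did not reach 1, and the 3 portions of one group did not overlap those of the other. Chance alone leaves 10% of unchanged transcripts without overlap in 3 against 3 values, before the other clauses. Intervals of ratios are exact conditional (Clopper-Pearson) intervals. They cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Where a group had 0 counts, the fold was computed against a floor of 3 counts over the group. Such a fold is not a bound, so the lower end of its 95% counting interval is printed with it. The floor was worth 1.03 CPM in input uninjured, 1.13 in input injured, 2.75 in IP uninjured and 2.88 in IP injured. The difference between the injury effects in IP and input was computed on the log2 scale for transcripts with at least 10 counts in all 4 groups. It was counted where it was at least 1 in size and its 95% counting interval, from a normal approximation on the log scale, excluded 0. Correlations across transcripts used log2 CPM with 1 count added.

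The rule for naming transcripts was reduced from 8 to at most 2 IDs per direction and comparison, taken as the largest folds among the counted transcripts, with the counting interval in place of an adjusted p. The size rule was tested on simulated counts with 100 transcripts changed 4-fold and 100 changed 8-fold per comparison. It recovered 93% and 96% of the 4-fold and 8-fold changes for injury in IP, 86% and 87% for injury in input, 85% and 83% for IP against input in uninjured ganglia, and 85% and 86% in injured ganglia. Unchanged transcripts were counted as different in 170 of 9239, 4 of 5789, 34 of 5885 and 27 of 5603 cases. These rates hold for the simulated counts and are not error rates of the deposited data. There, 2 portions of the same group differed at least 2-fold, without the clause on overlap, in 9.42% to 15.1% of transcripts. No simulated rate is given for the difference between injury effects.

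The alternatives were RLE size factors, no filter, a stricter filter, scaling of the compared groups alone, each portion left out in turn, and DESeq2, limma-voom with quality weights and a replicate block with the 3 samples as replicates. Added after seeing the data were library totals alone, scaling without the 2 most abundant IP transcripts, only transcripts whose portions agreed within counting noise, and the planned edgeR test on transcripts. The fits with the 3 samples as replicates used the planned level, an adjusted p under 0.05 with no fold minimum. They compared 9959 transcripts in edgeR and limma-voom and 1784 to 15614 in DESeq2, so their counts do not follow the size rule. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.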

Results

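RNA bound to tagged ribosomes of sensory neurons and input RNA of the dorsal root ganglion were compared with and without sciatic nerve injury, at the level of single transcripts. The 3 samples of a group had nearly equal totals of estimated counts. Input uninjured samples held 1685756, 1685278 and 1685126 counts, and input injured samples 1584104, 1585381 and 1584586. IP uninjured samples held 212449, 211497 and 212066 counts, and IP injured samples 190702, 190594 and 190664. The range within a group was 0.0374% to 0.449% of its mean.

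Among transcripts with at least 300 counts per sample, the median spread between the 3 samples was 1.34 times counting noise in input injured (727 transcripts) and 1.41 times in input uninjured (755). It was 0.945 times in IP injured (40 transcripts) and 1.34 times in IP uninjured (41). The median extra coefficient of variation, which is cut at 0, was 0 in each of the 4 groups for these transcripts. A minority of transcripts differed more, since 18.0% and 18.3% of these input transcripts had a chi-square p under the level that counting noise alone passes in 5%. The 3 samples of a group were counted as 1 sample and are called portions from here on. The summed totals were 5055830 counts in input uninjured, 4753793 in input injured, 635927 in IP uninjured and 571897 in IP injured.

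**Figure D1:**
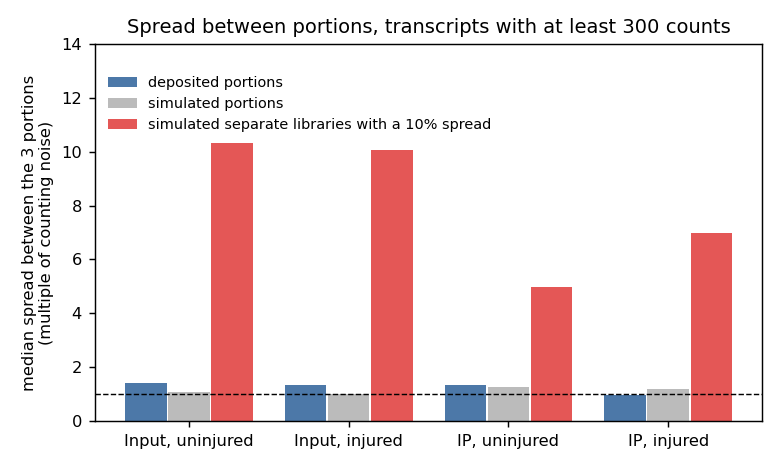
Median spread between the 3 portions of each group as a multiple of counting noise, for transcripts with at least 300 counts per portion. Blue bars are the deposited portions (0.945 to 1.41), grey bars are portions simulated with counting noise alone (1.00 to 1.25), red bars are separate libraries simulated with a 10% spread (4.97 to 10.3), and the dashed line marks 1.

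A pair of transcripts held a much larger share of the IP than of the input. Together they made up 24.2% of the counts in IP uninjured and 17.6% in IP injured, against 0.0742% and 0.0965% of the corresponding input. This pair was singled out after its values were seen. The more abundant of the 2 made up 12.3% of IP uninjured (exact 95% interval 12.3% to 12.4%) and 8.97% of IP injured (8.89% to 9.04%). In the input it made up 0.0339% (0.0323% to 0.0355%) and 0.0463% (0.0443% to 0.0482%). Its input portions held 551, 335 and 827 counts in uninjured and 871, 762 and 565 in injured ganglia. These intervals do not cover that spread, so its 2 input shares cannot be told apart. In input abundance the pair ranked 442 and 495 in uninjured and 395 and 426 in injured ganglia. The 10 most abundant transcripts held 30.9% and 26.6% of the IP counts in uninjured and injured ganglia, and 8.49% and 8.28% of the input counts. The 1000 most abundant transcripts held 67.9% and 66.4% of the IP counts in uninjured and injured ganglia, and 81.6% and 82.5% of the input counts. At a common depth of 571897 counts, 18112 and 17739 transcripts were detected in IP uninjured and injured, and 16815 and 16290 in the input.

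**Figure D2:**
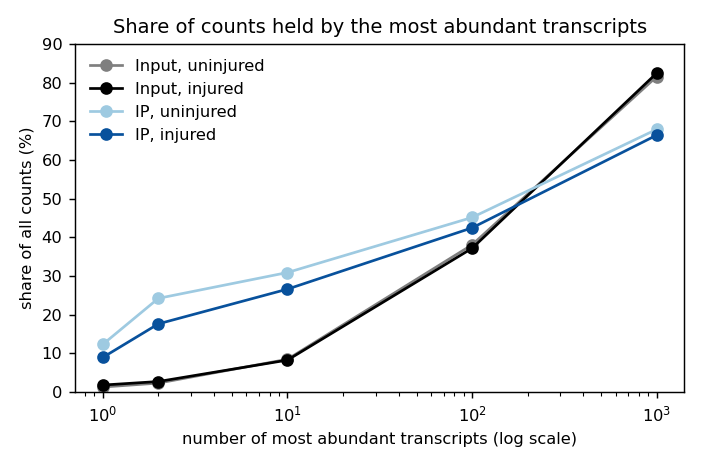
Share of all counts, in percent, held by the 1, 2, 10, 100 and 1000 most abundant transcripts of each group (log scale on the horizontal axis). The 2 most abundant transcripts held 24.2% and 17.6% of the IP counts and 2.33% and 2.74% of the input counts.

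The comparison of IP with input asks which RNAs the immunoprecipitation enriched. In uninjured ganglia, 1995 of 10236 compared transcripts were at least 2-fold higher in IP and 4076 at least 2-fold lower. The highest fold was that of ENSMUST00000196608.2, with 3011 counts in IP and 0 in input, 2676-fold higher against the floor (95% lower limit 2175). ENSMUST00000109262.8 had 1429 counts in IP and 5 in input, 762-fold higher (95% counting interval 326 to 2351). ENSMUST00000177513.2 had 0 counts in IP and 19424 in input, 2428-fold lower against the floor (95% lower limit 1975). ENSMUST00000107684.2 had 1 count in IP and 6198 in input, 2325-fold lower (417 to 91830). The portions of the last 3 of these transcripts differed beyond counting noise in at least 1 of the 4 groups, which need not be a group compared here. For ENSMUST00000109262.8 the uninjured input portions held 0, 4.88 and 0 counts, and the uninjured IP portions 460, 464 and 505.

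In injured ganglia, 1653 of 9718 compared transcripts were at least 2-fold higher in IP than in input and 3785 at least 2-fold lower. ENSMUST00000196608.2 had 7693 counts in IP and 2 in input, 9773-fold higher (2704 to 80711). ENSMUST00000109262.8 had 5787 counts in IP and 0 in input, 4901-fold higher against the floor (lower limit 3984). ENSMUST00000177513.2 had 3 counts in IP and 22723 in input, 2981-fold lower (1020.0 to 14457). ENSMUST00000163992.3 had 2 counts in IP and 7700 in input, 1515-fold lower (419 to 12515), and its portions agreed within counting noise in all 4 groups. Of the 8463 transcripts compared in both conditions, 978 were higher in IP in both, against 266 for independent lists, and 2986 were lower in both, against 1453. Another 12 were higher in uninjured and lower in injured ganglia, and 9 the reverse. The balance of higher and lower transcripts depended on the scaling. Transcripts higher in IP made up 32.9% of those that differed in uninjured and 30.4% in injured ganglia with TMM factors, and 68.3% and 73.7% with library totals alone. The median log2 fold moved from -0.51 and -0.56 to 1.72 and 1.85. Library totals alone multiply each ratio of IP to input given above, and its interval, by 2.98 in uninjured and 3.27 in injured ganglia.

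The comparison of injured with uninjured IP asks how the RNA recovered by IP differed after nerve injury. After injury, 965 of 8041 compared transcripts were at least 2-fold higher and 834 at least 2-fold lower. The change was at least 4-fold for 422 of the higher and 287 of the lower ones. Higher transcripts made up 53.6% of those that differed, and 60.8% with library totals alone, which moved the median log2 fold from -0.05 to 0.15. ENSMUST00000034215.8 had 4706 and 3929 counts in injured and uninjured input. In injured and uninjured IP it had 162 and 0 counts, 56.5-fold higher against the floor (lower limit 45.4). ENSMUST00000027941.14 had 73 and 2 counts, 38.2-fold higher (10.2 to 321). ENSMUST00000028300.6 had 0 and 183 counts, 58.3-fold lower against the floor (lower limit 47.0). ENSMUST00000112848.8 had 0 and 133 counts, 42.4-fold lower against the floor (lower limit 34.0). The portions of the last 3 differed beyond counting noise in injured input, which is not part of this comparison. They held 0, 39.8 and 35.9 counts there, then 0, 0 and 37.2, then 0, 0 and 5.21. The uninjured IP portions of the last 2 held 69.3, 56.1 and 57.2 counts, and 45, 49 and 38.7. A single portion of injured against uninjured IP differed at least 2-fold, without the clause on overlap, in 21.1% to 21.8% of transcripts, and 2 portions of the same IP group in 9.42% to 12.2%. Fits that took the 3 samples of a group as replicates counted 651 to 1244 transcripts, and in DESeq2, with 651, the higher ones made up 66.5%. IP levels correlated with input levels at r of 0.353 in injured and 0.205 in uninjured ganglia. Of the 729 higher transcripts compared in uninjured ganglia, 70.0% were at least 2-fold lower in IP than in input there. Counts drawn with counting noise and no injury effect gave 53.3%, over a mean of 40.25 transcripts per draw. That is the share among transcripts counted by noise alone, so it is not a null value for the 729. Whether the differences arose on sensory neuron ribosomes or in other RNA in the IP was not tested.

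In the input, which the labels call total RNA although their extraction text describes the immunoprecipitation, 832 of 9139 compared transcripts were at least 2-fold higher after injury and 677 at least 2-fold lower. ENSMUST00000054599.8 rose from 5 to 1844 counts, 405-fold (173 to 1248), and had 3 and 56 counts in uninjured and injured IP. ENSMUST00000165335.8 went from 0 to 504 counts, 184-fold higher against the floor (lower limit 149). ENSMUST00000030940.14 went from 493 to 0 counts, 150-fold lower against the floor (lower limit 121). The sum of these last 2 transcripts was 493 counts in uninjured and 504 in injured input. Their portions differed beyond counting noise in IP. The injured IP portions held 170, 228 and 0 counts of ENSMUST00000165335.8, and 168, 0 and 345 of ENSMUST00000030940.14. ENSMUST00000215434.2 went from 794 to 0 counts, 241-fold lower against the floor (lower limit 196). Its 3 uninjured portions held 155, 243 and 396 counts. Transcripts higher after injury made up 55.1% of those that differed. They made up 72.8% when only the input groups were scaled together, and 44.3% to 46.0% when any one of the injured input portions was left out. Single portions of injured against uninjured input differed at least 2-fold in 26.3% to 27.4% of transcripts, and 2 portions of the same input group in 14.6% to 15.1%. Fits that took the 3 samples of a group as replicates counted 463 to 2177 transcripts. Among these, edgeR counted 905, and 627 with the replicate number as a block. Higher transcripts made up 45.8% in limma-voom and 81.9% in DESeq2.

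The last comparison asks whether the difference with injury was another one in RNA recovered by IP than in input RNA. Of 5689 transcripts compared for injury in both, 218 were higher in IP and in input, against 55.6 for independent lists, and 65 were lower in both, against 27.4. Of 4924 transcripts with enough counts in all 4 groups, 539 had a log2 injury effect higher by at least 1 in IP than in input, and 460 had one lower by at least 1. The higher ones made up 54.0% of these, 45.8% to 62.0% with 1 portion left out and 80% with the replicate block. Across 11491 transcripts, which are not independent replicates, the log2 injury folds of IP and input had a Pearson r of 0.127 and a Spearman rho of 0.181. Across the 1085 transcripts with at least 50 counts in all groups, r was 0.460 and rho 0.378. The count of differing injury effects fell to 649 among transcripts whose portions agreed within counting noise, and was 80 to 478 in fits that took the 3 samples of a group as replicates.

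**Figure D3:**
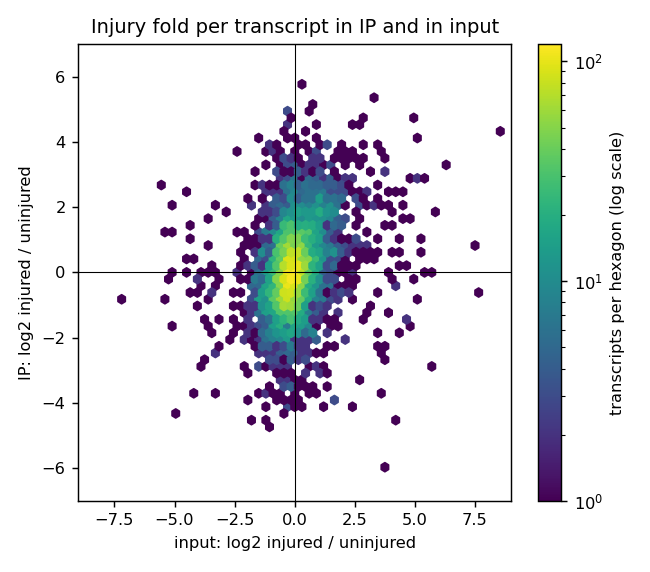
Log2 ratio of injured to uninjured for each of the 5689 transcripts compared in both IP (vertical axis) and input (horizontal axis); colour gives the number of transcripts per hexagon on a log scale. Of these, 218 were at least 2-fold higher after injury in both and 65 at least 2-fold lower in both.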

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

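The 2 tests on the equal totals were chosen after the result was seen, and the second test on partner transcripts was added after the first had proved uninformative. In opposite directions in IP and input, every portion agreeing, were 22 transcripts that differed at least 2-fold with injury. Of these, 14 were higher in IP and lower in input and 8 the reverse, against 40.6 and 37.5 for independent lists, and the difference itself was not tested across animals.

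The 3 samples of each group had totals within 0.449% of each other. A set of 3 separate libraries reduced to one depth would keep a spread in abundant transcripts. With at least 300 counts the median extra coefficient of variation, which is cut at 0, was 0% in every group. Separate libraries simulated with a 10% spread gave 6.05% to 8.28%, which argues against a spread of that size. A smaller spread was not simulated and is not excluded. Input uninjured transcripts with 30 to 100 counts had 3.35%. With at least 300 counts the largest median spread over the 4 groups was 1.41 times counting noise. In narrower count ranges it reached 1.65 (IP injured, 100 to 300 counts). Portions simulated with counting noise alone gave 1.00 to 1.25, and simulated separate libraries 4.97 to 10.3. By this median the deposited values lie nearer to 1 library divided into 3 portions. Across 11491 transcripts, portions 1 and 2 correlated at r of 0.814 in input injured and 0.808 in input uninjured. In IP injured and uninjured they correlated at 0.761 and 0.758. Input uninjured thinned to the lower IP depth correlated with the rest of the input at 0.953. The input portions thus scattered more than counting noise alone, and whether they are 1 library was not settled. A tail of transcripts differed more, edgeR's common biological coefficient of variation over 9959 transcripts was 35.6%, the labels give 3 samples, and same-numbered injured and uninjured input samples had r of 0.169 to 0.258, against -0.253 to 0.0372 for differently numbered ones. No biological explanation was tested.

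That tail held 8.10% and 8.94% of input injured and uninjured transcripts with at least 10 counts per portion, at a chi-square p under 1e-04. One explanation is that the quantification moved estimated counts between similar transcripts. A first search for partners whose sum agreed within counting noise exceeded rotated controls by only 1.40 percentage points in the lowest group, but 95.3% to 98.0% of the controls also had a partner, so it cannot be told apart from chance. Requiring the same partner in both input groups gave 70.8% of 267 transcripts against 54.4% for rotated partners, a difference of 16.4 points, in line with this explanation, and in both IP groups 46.6% of 58 against 20.3%, 26.3 points. Deviations shared between samples of the 2 groups would also raise the difference. In IP, same-numbered samples had r of -0.406 to -0.0893, but differently numbered ones had -0.349 to 0.458. Shared deviations are therefore not excluded in input or in IP. Neither similarity of sequence nor a biological explanation was tested.

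IP and input levels correlated weakly across 11491 transcripts, with r of 0.205 in uninjured and 0.353 in injured ganglia. Input uninjured thinned to the IP depth correlated with the rest of the input at 0.953. Thinning adds counting noise only, and the deposited portions scattered more. Portions 1 and 2 correlated at 0.814 and 0.808 in input injured and uninjured, and at 0.761 and 0.758 in IP injured and uninjured. These values argue against counting noise at the lower IP depth as the cause, and cover no other effect of depth. Among transcripts whose portions agreed within counting noise the larger r was 0.388, which argues against counts that move between portions, though not against an assignment that differs steadily between IP and input. With at least 50 counts in all groups r was 0.254 and 0.529. Different cell content of the 2 RNA fractions, differences in amplification and a library effect stay open and were not tested.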

How the results depend on the processing

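Alternatives chosen after seeing the data were library totals alone, scaling without the 2 top IP transcripts, transcripts with agreeing portions alone and the edgeR test. With the summed portions, 33 of 35 other counts lay within 1.5 times the reported count. These include scaling of the compared groups alone for the difference of effects, which is the same setting as the reported one. The exceptions were 2346 for injury in input without a filter against 1509, where more transcripts were compared, and 649 against 999 for the difference of injury effects with agreeing portions alone, where fewer were. Leaving out 1 portion gave 1902 to 2011 for injury in IP (1799 reported), 1741 to 1849 for injury in input, 6172 to 6336 and 5561 to 5643 for IP against input in uninjured and injured ganglia (6071 and 5438), and 820 to 996 for the difference of effects. The clause on overlap, which the difference of effects does not use, is easier to meet with fewer portions. The higher counts in the other comparisons therefore cannot show that the reported ones are stable. For the difference of effects, the share of higher effects, 54.0%, ranged from 45.8% to 62.0% with 1 portion left out. It was 65.6% with library totals alone, 68.2% in edgeR, 76.1% in DESeq2 and 80% with the replicate block. With the samples as replicates, 10 of 20 counts moved further. These fits used an adjusted p without a fold minimum and other sets of transcripts, so their counts are not like for like with the reported ones. How much of the movement comes from this was not tested. edgeR gave 905 for injury in input and 453 for the difference. limma-voom gave 1184 for injury in IP and 478 for the difference. DESeq2 gave 651, 463 and 255 for injury in IP, injury in input and the difference. The replicate block gave 926, 627 and 80, and 4530 and 3901 for IP against input. Whether the numbers are pairs for injury in input was not settled. Elsewhere same-numbered samples had r of -0.406 to 0.266. Gene lists, isoform usage and scaling without mitochondrial genes were not run, since transcripts were not matched to genes, and the pseudocount alternative did not apply to counts. Depth limits the IP most, where 3 counts equal 2.75 to 2.88 CPM.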

Other observations

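The tables of injury changes by IP enrichment and the pair of input transcripts were chosen after the data were seen. Each injury comparison shares a group with the enrichment it is set against, so 20 draws with counting noise and no injury effect are given beside the shares, and they hold far fewer transcripts than observed. Each share is over the transcripts that also reached 10 CPM in IP or input of the condition named, a filter that the injury change itself affects. Of the 832 transcripts higher in input after injury, 534 were compared in uninjured ganglia, and 341 of them (63.9%) were at least 2-fold lower in IP than in input. Independent lists would share 259, and the draws gave 1.48%. Of the 677 lower in input after injury, all compared there, 426 (62.9%) were lower in IP, against 328 for independent lists and 45.2% in the draws. In injured ganglia, 601 of the 832 higher transcripts (72.2%) and 151 of the 385 lower ones compared there (39.2%) were lower in IP, against 379.5 and 176 for independent lists and 41.0% and 0% in the draws. With library totals alone for both comparisons, these 4 shares were 52.2%, 49.8%, 57.9% and 21.9%.

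Of the 965 transcripts higher in IP after injury, 390 (40.4%) were at least 2-fold lower in injured IP than in injured input, against 229.9 for independent lists and 13.5% in the draws. Of the 834 lower in IP after injury, 552 were compared in injured ganglia and 148 of them (26.8%) were lower in IP than in input, against 132 for independent lists and 54.4% in the draws. In uninjured ganglia, 510 of the 729 higher transcripts compared there (70.0%) and 59 of the 834 lower ones (7.07%) were lower in IP, against 173 and 198 for independent lists and 53.3% and 13.5% in the draws. With library totals alone these 4 shares were 23.4%, 9.88%, 48.4% and 2.22%, and 56.1% of the transcripts higher in IP after injury were then at least 2-fold higher in injured IP than in injured input, against 25.4% with TMM factors.

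Leaving the 2 most abundant IP transcripts out of the scaling moved the median log2 ratio of IP to input in uninjured ganglia by 0.105, from -0.51 to -0.41. In injured ganglia the median moved from -0.56 to -0.36. In the input the 2 transcripts varied between portions, while their sum stayed within counting noise, with chi-square values of 1.74 and 0.527.

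ENSMUST00000165335.8 and ENSMUST00000030940.14, named for opposite changes in input, had 398 and 513 counts in IP injured and 608 and 885 in IP uninjured. Their sum in input was 170 CPM in uninjured and 190 CPM in injured ganglia. Between portions the sum stayed within counting noise in both input groups and in IP uninjured, with chi-square values of 0.179 at the lowest and 0.580 at the highest. In each input group 1 of the 2 transcripts had 0 counts. The sum there is the other transcript alone and cannot show whether counts were exchanged. In IP injured the sum was 338, 228 and 345 counts, with a chi-square of 28.3, which goes against an exchange of counts between these 2 transcripts alone in that group.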
